A study of Macaca fascicularis with 101 samples.

How the data were processed

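Single cells from the aortic arch and the coronary arteries of 16 cynomolgus monkeys (Macaca fascicularis) were profiled, 8 animals aged 4 to 6 years (young) and 8 aged 18 to 21 years (old), with 4 females and 4 males in each age group. Per the labels' protocols, the arteries were cut into fragments and digested with collagenase, dispase and elastase, and the suspension was parted into CD31-positive and CD31-negative cells by flow cytometry. CD31 is the surface protein encoded by PECAM1, which endothelial cells carry. Single cells were then picked into lysis buffer and processed by a variant of Smart-seq2 with barcoded reverse transcription primers, so that up to 96 cells were pooled into 1 library, per the labels' protocols. Libraries are named here by artery, gate and animal, and the letters p and n in the library titles were read as the CD31-positive and CD31-negative gate. The values bear that reading out. In the aorta PECAM1 had 2443 CPM (UMI counts scaled to a common total) in cells of the p gate and 33.7 in cells of the n gate. In the coronary arteries the same values were 2694 and 127.2.

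The deposited unit is a raw UMI count per gene and cell, with no normalization, per the file headers and the submitters' processing notes. Those notes name CASAVA 1.8, TopHat2 2.0.12 and HTSeq. They give hg19 as the genome build, while the submitters' description of the files names the cynomolgus assembly with an Ensembl annotation to which genes such as FOXO3 were added. The gene identifiers are those of the cynomolgus annotation. No coordinates are given here because the build was not settled. The 101 files held 21136 entries each, of which 95 were spike-in or construct sequences and 21041 were genes. Gene symbols were taken from a second deposited table of the same counts, whose genes carry symbols. Identifiers and symbols were paired where a gene's counts were equal in both, which paired 15958 identifiers uniquely and gave 13401 gene names with a symbol. In the 8 libraries with 760 cells present in both, 0 genes had unequal counts.

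Of 9071 cells in the files, 7989 carried a cell type in the deposited annotation, and these were analysed. Their UMI totals had a minimum of 3006 and their gene numbers a minimum of 1001. Of the other 1082 cells, 413 reached both minima, and they were left out of all comparisons. No doublet caller was run, because cells were picked singly, per the labels' protocols. Of 4744 annotated endothelial cells, 2 reached the marker level of more than 1 class, with 41 of 1525 smooth muscle cells and 30 of 1161 fibroblasts. The authors' endothelial labels (1 aortic, 2 coronary) were merged, as were their aortic and coronary smooth muscle labels, and cells of a class were assigned to the artery of their library. The remaining classes were fibroblasts, immune cells, lymphatic endothelial-like cells and epicardial cells. Columns of 18 human cell-line samples and 5216 barcodes of a human cell-line matrix belong to no monkey sample and were not used here. Among the genes with a symbol there was no XIST, Y-linked gene or haemoglobin gene, so the sex labels could not be checked against the data. No 2 cells had identical columns, and every pair of libraries of a group differed beyond counting error, with a smallest chi-square per degree of freedom of 11.3.

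The replicate was the animal. UMI counts of genes were summed per animal, artery and class over animals with at least 10 cells, and a comparison was tested where each group kept at least 4 animals. Sums were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F-test with TMM normalization, filterByExpr as the filter on low counts and Benjamini-Hochberg adjustment at 0.05. Sex was a covariate of the age comparisons, and age group and sex were covariates of the comparison of arteries. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values are means over animals with their SD, from TMM-scaled totals. Artery fold changes are coronary over aorta. All adjusted p of single genes come from this test unless another is named. Interaction terms asked whether the age change differed between arteries or between sexes.

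The same 16 animals gave both arteries, as the animal numbers in the labels show. The deviations of an animal's 2 arteries from their group means correlated across genes with a mean r of 0.21 in endothelial cells, 0.119 in smooth muscle cells and 0.111 in fibroblasts. Genes are not independent replicates. The fit without a block was the main one, and the fit with the animal as a block was its alternative.

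Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, where at least 5 members were measured. There were 40 gene lists, between 32 and 35 of them tested per comparison, adjusted together by Benjamini-Hochberg. Shares of cell types, depth per cell and cell-to-cell variability were compared between animals with two-sided exact permutation tests of the difference of means, which enumerate 12870 regroupings for 8 against 8 animals. Variability was the mean of 1 minus Pearson's r of log1p counts over pairs of an animal's cells thinned to 10000 UMIs. Some cells lay below that depth and could not be thinned to it. In coronary endothelial cells these were 92 of 835 cells of young and 111 of 1113 of old animals. The permutation tests and these measures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

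The following were fixed before the data were examined: the tests, the gene lists, the alternatives and the rule for the genes named. That rule takes up to 10 genes per direction with adjusted p under 0.05, a mean of at least 10 CPM and a symbol, ranked by p, and up to 4 members with the smallest p of each list that passed camera or had at least 2 members past the threshold. If fewer than 5 genes pass, it takes the 5 genes with a symbol and the smallest p, and for interactions also 5. The script counted as passing only genes that also had the mean CPM and a symbol, 3 of the 6 changed in aortic endothelial cells, so NDST3 and ZBTB16 are named there on that reading. FOXO3, CDKN1A, CDKN2A, LMNA, SIRT1 and NOS3 were to be reported whatever their p, and this was done for age and artery but not for the interactions. CDKN2A passed the filter in no comparison of age or artery. Which of the lists that met the rule are described in full was chosen after their results were seen. The names outside the rule are identified where they appear.

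Several analyses were added after the data had been seen: fits of single endothelial and smooth muscle labels, fits with lymphatic endothelial-like cells, the age comparison with both arteries in 1 fit, the ratio of gene UMIs to spike-in UMIs and the tests of explanations in the closing part. The fit of both arteries used limma on voom values with artery and sex as covariates and a common correlation within an animal, which was estimated from every 10th gene for speed. The other settings tried, fixed beforehand, were DESeq2 1.42.0, median-of-ratios (RLE) size factors, no filter, at least 20 cells per animal, no sex covariate, 1 gate only, 10 cells drawn per animal, limma-trend on mean log2(CPM + 1) per cell with a pseudocount of 1, age in years and each animal left out in turn.

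The edgeR test was tested on simulated data, with counts drawn from the real means, dispersions and totals and 200 genes changed by known folds. Of the genes changed 4-fold by age it recovered 67% in aortic and 62% in coronary endothelial cells, 40% and 45% in smooth muscle cells and 48% and 35% in fibroblasts. Of the genes changed 2-fold it recovered 33% and 17%, 3% and 10%, and 8% and 4%, in the same order. For the comparison of arteries the recovery of 4-fold changes was 75% in endothelial cells, 64% in smooth muscle cells and 55% in fibroblasts. For the age by artery interaction it was 48%, 21% and 17%. Both of these simulations drew the arteries of an animal independently of each other, unlike the paired real data. A list raised 1.5-fold was found in every comparison with the preset correlation, and with an estimated correlation in every comparison but the interaction in smooth muscle cells. The simulated genes varied independently, so this does not show how either setting behaves where genes vary together. In the real data, other splits of the animals by age passed a median of 4 to 6 lists with the preset correlation. The fit of both arteries was simulated with an added SD of 0.3 (log2) between animals. In endothelial cells 8 of its 123 calls were false and in smooth muscle cells 6 of 95. In fibroblasts it was 11 of 85, and all 3 shares lie above the nominal 5%. For age within 1 artery it was 6 of 106 and 3 of 82 in aortic and coronary endothelial cells, 2 of 45 and 0 of 55 in smooth muscle cells and 1 of 57 and 4 of 43 in fibroblasts.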

Results

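Transcripts of single cells were counted in the aortic arch and the coronary arteries of 16 cynomolgus monkeys to ask how the cells of both arteries change with age and how the arteries differ. The 101 libraries held 21 to 96 cells each and 9071 cells together. Aortic cells came from 26 libraries of young animals (2214 cells, of which 2020 carried a cell type) and 27 of old animals (2547 and 2363). Coronary cells came from 23 libraries of young animals (1932 and 1638) and 25 of old animals (2378 and 1968). The total of gene UMIs per library had a median of 4924935. It ranged from 614078 to 13682230 in young aorta, from 2342340 to 11807103 in old aorta, from 349748 to 6343881 in young coronary and from 1607248 to 11824197 in old coronary libraries. An annotated cell had a median of 47530 UMIs and 3053 genes. The classes large enough for tests were endothelial cells (2796 aortic, 1948 coronary), smooth muscle cells (636 and 889) and fibroblasts (762 and 399). The tested animals had between 83 and 349 aortic endothelial cells each, but as few as 10 aortic smooth muscle cells and 11 coronary fibroblasts.

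The sort set the classes that each library could hold. Of the CD31-positive cells, 97.5% were endothelial in the aorta and 89.5% in the coronary arteries, where a further 7.82% were lymphatic endothelial-like cells. CD31-negative cells were 40.8% smooth muscle and 49.0% fibroblasts in the aorta, and 58.7% and 26.7% in the coronary arteries. Shares therefore describe picked cells within a gate. In the coronary CD31-positive gate the authors' second coronary endothelial label made up 49.6% ± 31.3 (SD, n = 8) of the annotated cells of young animals and 19.8% ± 6.21 (SD, n = 8) of old animals (exact permutation p = 0.0242, adjusted over the 5 types of the gate 0.0606). The first coronary label had 41.2% ± 35.5 in young and 66.2% ± 12.7 in old animals (exact permutation p = 0.083, adjusted 0.138). Cells with the aortic endothelial label were rare in coronary libraries, at 0.373% ± 0.83 in young and 3.17% ± 3.31 in old animals (exact permutation p = 0.0118, adjusted 0.0591). No share passed the adjusted threshold in any of the 4 pairs of artery and gate. With the libraries of both gates pooled, 2 of these differences passed it, that of the aortic label (adjusted exact permutation p = 0.0472) and that of the first coronary label (0.0497). A pooled share also depends on how many cells of each gate an animal gave. Of the annotated coronary cells, 16 of 83 were CD31-positive in young CE06 and 183 of 273 in old CE10. The pooled differences therefore cannot be told apart from the mix of gates.

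**Figure D1:**
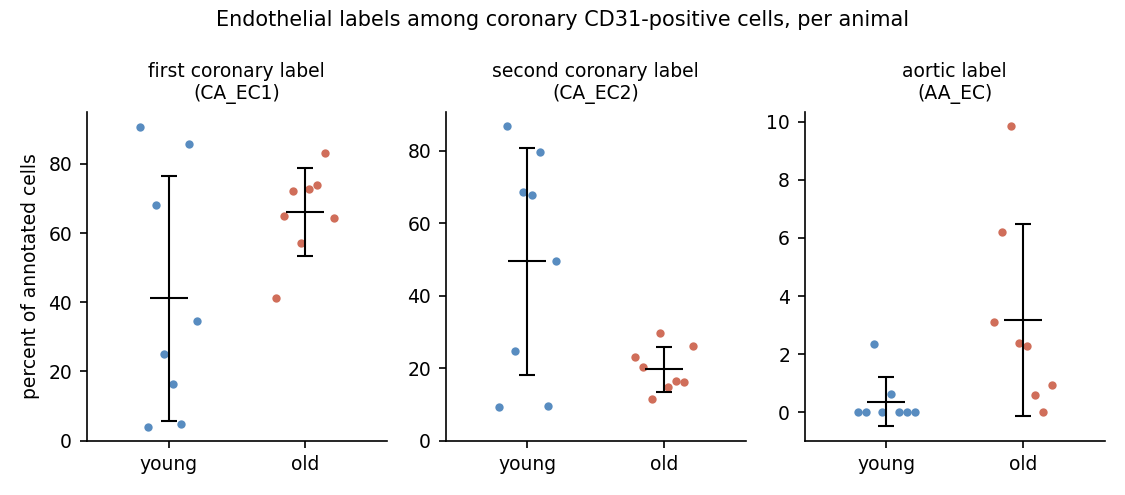
Percent of annotated cells that carried each endothelial label in CD31-positive coronary libraries, with 1 point per animal and the mean and SD over 8 young and 8 old animals. The second coronary label lay at 49.6% in young and 19.8% in old animals on average, a difference that did not pass the adjusted threshold.

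Aortic endothelial cells of old animals had a lower share of counts from 3 surface and basement membrane genes. LAMB2 (ENSMFAG00000030537), which encodes a laminin chain of the basement membrane, fell by 1.01 ± 0.15 on the log2 scale (SE), from 226 ± 69.0 CPM in young animals to 109.8 ± 17 in old animals (SD, n = 8 each). MERTK (ENSMFAG00000032328), a receptor tyrosine kinase that mediates the uptake of dying cells, fell by 1.36 ± 0.21, from 58.8 ± 20.5 to 22.9 ± 5.22 CPM. LIFR, the receptor of leukaemia inhibitory factor, fell by 0.96 ± 0.17, from 138 ± 40.3 to 70.4 ± 13.4 CPM. NDST3, a sulfotransferase of heparan sulfate, had 0.156 ± 0.165 CPM in young and 17.2 ± 21.0 in old animals, and was named among the 5 genes with the smallest p since its mean lies under 10 CPM. ZBTB16, a zinc finger transcription factor, had the next smallest p, with a log2 fold change of -1.44 ± 0.27 that did not pass.

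By edgeR's quasi-likelihood test, adjusted p was 0.00456 for LAMB2, 0.00712 for MERTK, 0.0285 for LIFR, 0.00712 for NDST3 and 0.0655 for ZBTB16, over 11582 genes. A total of 6 genes changed, 2 up and 4 down, and the remaining 2 have no symbol. At an unadjusted p under 0.05 there were 837 genes where chance gives 579, and DESeq2 called 76. The FOXO3 transcript, which encodes a forkhead transcription factor of stress resistance and longevity, had 227 ± 148 CPM in young and 93.1 ± 20.9 in old animals, a log2 fold change of -1.10 ± 0.23 with adjusted p = 0.0733. CDKN1A, LMNA, SIRT1 and NOS3 had log2 fold changes of 0.72 ± 0.34, 0.05 ± 0.16, -0.07 ± 0.26 and -0.04 ± 0.33, with adjusted p of 0.7 and above. Of 54 ribosomal protein genes 53 had a positive fold change, with a median of 0.26, and the list passed camera with the preset correlation (adjusted p = 6.3e-20) but not otherwise (adjusted p = 0.66 with an estimated correlation). None of its members passed over all genes, and 12 rose when adjusted over the list alone, led by RPS24 (0.54 ± 0.16) and RPL7A (0.46 ± 0.14). The list of oxidative phosphorylation genes had 33 of 38 members positive with a median of 0.14 and passed with the preset correlation (adjusted p = 0.000779), though adjusted p = 0.66 with an estimated correlation. It had 0 members past the threshold of edgeR over all genes and 0 adjusted over the list alone. LAMB2, MERTK and LIFR did not pass with 10 cells drawn per animal (adjusted p of 0.802, 0.814 and 0.896), where their log2 fold changes were as large but less precise (-1.10 ± 0.47, -2.02 ± 0.90 and -1.09 ± 0.55). MERTK, LIFR and NDST3 did not with limma-trend (-1.13 ± 0.25, -1.30 ± 0.34 and 0.67 ± 0.25, adjusted p of 0.1, 0.163 and 0.387). LIFR did not without animal CE01, CE09, CE10, CE13, CE16 or CE17 (-0.98 to -0.88, adjusted p from 0.0587 to 0.103). The count of changed genes was 10 without CE07, 13 without CE14, 12 without CE04, 16 without CE03, and 4 without CE09 or CE17.

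In coronary endothelial cells MT1X (ENSMFAG00000035516), a metallothionein that binds zinc and copper, fell by 1.72 ± 0.24 on the log2 scale, from 1334 ± 969 CPM in young animals to 377 ± 69.9 in old animals (SD, n = 8 each). It was the only gene of 10928 to pass edgeR's test (adjusted p = 0.00162), with 800 genes at an unadjusted p under 0.05 against 546 by chance and 80 called by DESeq2. The genes with the next smallest p did not pass. BAIAP2 had a log2 fold change of -1.86 ± 0.34 (adjusted p = 0.0502) and NOSTRIN, which binds endothelial nitric oxide synthase, one of -1.27 ± 0.24 (adjusted p = 0.0673). CASTOR1, an arginine sensor of the mTORC1 pathway, had -1.22 ± 0.25, and HPS3, a subunit of a lysosome biogenesis complex, had 3.06 ± 0.61, both with adjusted p = 0.0804. FOXO3 had -0.73 ± 0.22, from 282 ± 89.4 to 167 ± 58.0 CPM, with adjusted p = 0.294. CDKN1A, LMNA, SIRT1 and NOS3 had 0.13 ± 0.38, 0.35 ± 0.19, -0.79 ± 0.39 and 0.57 ± 0.39.

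Of 32 lists tested in coronary endothelial cells, 9 passed camera with the preset correlation and 0 passed with an estimated correlation or by fry. Among 14 venous and capillary identity genes 13 had a negative fold change, with a median of -0.53 (adjusted p = 0.0125, and adjusted p = 0.638 with an estimated correlation). None passed over all genes and 1 fell when adjusted over the list alone, the fatty acid transporter CD36 (-1.63 ± 0.42). The 14 arterial identity genes had 11 positive members and a median of 0.28 (adjusted p = 0.0379, and adjusted p = 0.638 with an estimated correlation), with HEY2 at 0.93 ± 0.34 and EFNB2 at 0.56 ± 0.22 and 0 members past edgeR's threshold over all genes or adjusted over the list alone. In the same animals the second coronary label went from 49.6% of the CD31-positive cells in young to 19.8% in old animals. The 54 ribosomal protein genes had 52 positive members and a median of 0.25 (adjusted p = 4.51e-09, and adjusted p = 0.638 with an estimated correlation), with 0 members past either adjustment. MT1X had -1.18 ± 0.22 with an adjusted p of 0.0847 in cells of the second coronary label alone, a fit added after the data were seen. The count of changed genes was 3 without CE01, CE04, CE09 or CE10, 4 without CE06, 5 without CE05, 7 without CE17 and 8 without CE14.

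**Figure D2:**
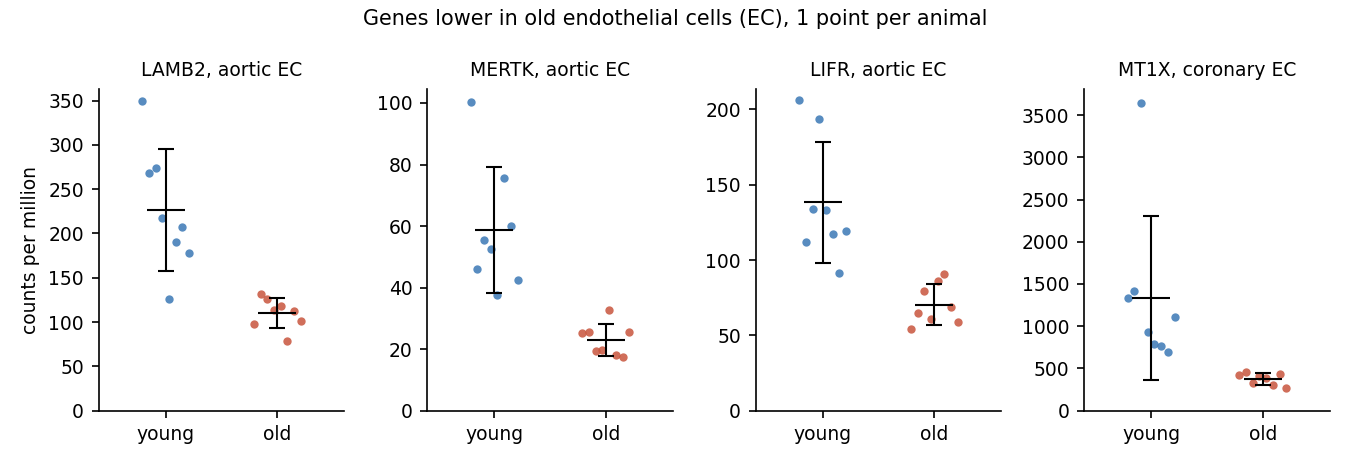
CPM of 3 genes in aortic and 1 gene in coronary endothelial cells (EC), with 1 point per animal and the mean and SD over 8 young and 8 old animals. Old animals averaged 109.8 CPM of LAMB2, 22.9 of MERTK, 70.4 of LIFR and 377 of MT1X, each lower than in young animals by edgeR's test.

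Aortic smooth muscle cells gave no gene past edgeR's threshold among 9608 tested, in 6 young and 7 old animals. The genes with the smallest p all had adjusted p = 0.273. MGLL, a lipase of monoacylglycerols, had a log2 fold change of 2.18 ± 0.48, SNCG, a synuclein, had 3.87 ± 0.85, MYOC, the secreted protein myocilin, had -2.55 ± 0.55, and LAMA2, a laminin chain, had -3.44 ± 0.75. RIC3, a chaperone of acetylcholine receptors, was at 0 CPM in young and 11.6 ± 13.3 CPM in old animals. FOXO3 had -0.36 ± 0.25, and CDKN1A, LMNA and SIRT1 had 0.77 ± 0.46, 0.21 ± 0.23 and 0.03 ± 0.61, all with adjusted p of 0.998 and above. The count of 0 from edgeR compares with 483 genes at an unadjusted p under 0.05, 480 by chance and 34 called by DESeq2. It was 1 without CE07 and 8 without CE14.

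All 15 fibroblast identity genes measured in aortic smooth muscle cells had a negative fold change, with a median of -1.07 (camera adjusted p = 8.17e-08, and adjusted p = 0.567 with an estimated correlation). None passed over all genes and 8 fell when adjusted over the list alone, among them COL1A2 (-1.05 ± 0.27), SERPINF1 (-2.13 ± 0.50), MFAP5 (-2.22 ± 0.52) and GSN (-0.85 ± 0.22). The 20 genes of inflammatory cytokines and adhesion molecules had 5 positive members and a median of -0.98 (adjusted p = 4.74e-06, and adjusted p = 0.567 with an estimated correlation), with 0 past edgeR's threshold over all genes. Adjusted over the list alone 3 fell, led by the chemokines CXCL3 (-4.30 ± 1.17) and CCL2 (-1.93 ± 0.59). Macrophage genes moved with them, all 12 negative with a median of -1.53 (adjusted p = 0.0145, and adjusted p = 0.598 with an estimated correlation). With the preset correlation 7 of 32 lists passed.

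Coronary smooth muscle cells likewise gave no gene past edgeR's threshold among 10202 tested, in 8 young and 7 old animals. COL1A1, a chain of type I collagen, came closest, with a log2 fold change of -1.36 ± 0.25 from 601 ± 245 CPM in young to 226 ± 62.7 in old animals (adjusted p = 0.11). ID1, an inhibitor of DNA binding downstream of BMP signals, had 0.91 ± 0.18 (adjusted p = 0.21). COL3A1 had -1.15 ± 0.26, the matrix protease MMP2 -1.79 ± 0.42 and PDZD4 -4.94 ± 1.21, with adjusted p of 0.439 to 0.473. FOXO3 had -0.28 ± 0.19, and CDKN1A, LMNA, SIRT1 and NOS3 had 0.32 ± 0.22, 0.11 ± 0.18, 0.23 ± 0.39 and -0.24 ± 1.23. There were 493 genes at an unadjusted p under 0.05 against 510 by chance, and DESeq2 called 15. All 24 collagen genes had a negative fold change, with a median of -0.60 (camera adjusted p = 2.38e-06, and adjusted p = 0.194 with an estimated correlation), and 4 fell when adjusted over the list alone while 0 passed edgeR's threshold over all genes. Elastic fibre genes had 13 of 14 members negative and a median of -0.59 (adjusted p = 1.68e-05, and adjusted p = 0.314 with an estimated correlation), among them MFAP5 (-2.11 ± 0.60) and the fibrillin FBN1 (-0.73 ± 0.24), with 0 past over all genes and 2 lower when adjusted over the list alone. Fibroblast identity genes moved with both lists, with 14 of 15 negative and a median of -1.17 (adjusted p = 1.32e-08, and adjusted p = 0.418 with an estimated correlation). The count of 0 was 1 without CE01, CE14 or CE09.

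Aortic fibroblasts gave no gene past edgeR's threshold among 10294 tested, in 7 young and 8 old animals. COL14A1, a collagen that binds fibrils, had a log2 fold change of -1.29 ± 0.27, from 889 ± 301 CPM in young to 372 ± 138 in old animals, and the laminin chain LAMA2 had -1.11 ± 0.23, both with adjusted p = 0.164. SPARC, a matrix protein that binds collagen, had -1.11 ± 0.25 (adjusted p = 0.281), FAM13A -1.30 ± 0.25 (adjusted p = 0.127) and RUNDC3B 4.10 ± 0.76 (adjusted p = 0.121). FOXO3 had -0.70 ± 0.24 (adjusted p = 0.822), and CDKN1A, LMNA and SIRT1 had 0.05 ± 0.54, 0.29 ± 0.26 and 0.16 ± 0.47. There were 488 genes at an unadjusted p under 0.05 against 515 by chance, and DESeq2 called 10. Of 24 collagen genes 19 had a negative fold change, with a median of -0.26 (camera adjusted p = 1.83e-09, and adjusted p = 0.258 with an estimated correlation). None passed over all genes and 7 fell when adjusted over the list alone, led by COL14A1, COL6A2 (-0.66 ± 0.19) and COL5A2 (-0.92 ± 0.28). Macrophage genes had 10 of 13 members negative with a median of -0.46 (adjusted p = 4.68e-05, and adjusted p = 0.589 with an estimated correlation). The count of 0 was 4 without CE14, CE10 or CE13.

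In coronary fibroblasts COL1A1 (ENSMFAG00000033990) fell by 1.5 ± 0.25 on the log2 scale, from 3736 ± 931 CPM in 8 young animals to 1364 ± 756 in 7 old animals (SD). It was the only gene of 8360 past edgeR's threshold (adjusted p = 0.015). The other large fibrillar collagens lay the same way without passing. COL3A1 had a log2 fold change of -1.37 ± 0.27 (adjusted p = 0.116) and COL1A2 one of -0.96 ± 0.21 (adjusted p = 0.228). PCDH10, a protocadherin, had 2.39 ± 0.55 and ZBTB16 had -2.50 ± 0.60, with adjusted p of 0.339 and 0.356. FOXO3 had -0.93 ± 0.24, from 450.3 ± 128 to 234 ± 66.1 CPM (adjusted p = 0.368), and CDKN1A, LMNA and SIRT1 had 0.36 ± 0.37, -0.03 ± 0.24 and -0.66 ± 0.69. There were 431 genes at an unadjusted p under 0.05 against 418 by chance, and DESeq2 called 14. The collagen list had 15 of 23 members negative and a median of -0.31 (camera adjusted p = 3.08e-05, and adjusted p = 0.302 with an estimated correlation), with COL1A1 past over all genes and 6 members lower when adjusted over the list alone. Oxidative phosphorylation genes had 32 of 38 members positive and a median of 0.19 (adjusted p = 6.51e-06, and adjusted p = 0.302 with an estimated correlation). None of them passed over all genes and 1 rose when adjusted over the list alone, NDUFS7 (1.05 ± 0.25). COL1A1 did not pass without CE06, CE03, CE11, CE12 or CE17, with log2 fold changes from -1.50 to -1.38 and adjusted p from 0.0511 to 0.104. It did not pass with at least 20 cells per animal either (-1.57 ± 0.35, adjusted p = 0.41). That fit kept 4 young and 3 old animals, which is under the minimum of 4 per group set for comparisons. The count of changed genes was 2 without CE14, CE09 or CE13.

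**Figure D3:**
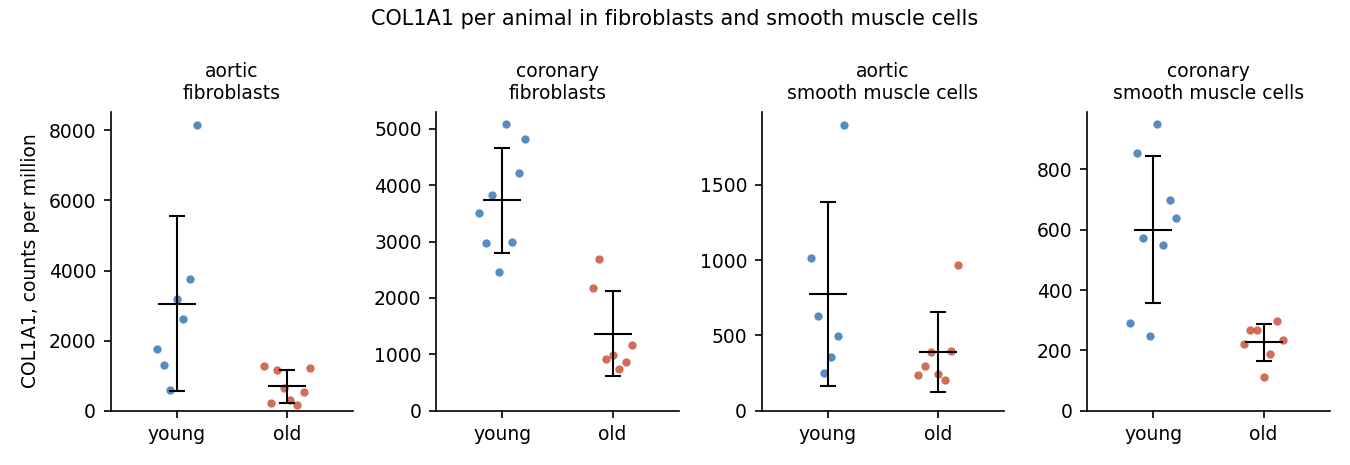
COL1A1 CPM in fibroblasts and smooth muscle cells of both arteries, with 1 point per animal and the mean and SD per age group. In coronary fibroblasts the mean was 3736 CPM in 8 young and 1364 CPM in 7 old animals, the 1 difference among those drawn that passed edgeR's test.

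With both arteries in 1 fit, which was added after the data were seen, 125 genes changed in endothelial cells, 67 up and 58 down, among 11809 tested in 16 animals. MT1X fell by 1.77 ± 0.20 on the log2 scale (limma, adjusted p = 3.41e-06) and ZBTB16 by 1.35 ± 0.20 (0.000206). FOXO3 fell by 1.00 ± 0.18 (limma, adjusted p = 0.00214), and TSC22D3, a leucine zipper protein that glucocorticoids induce, by 0.71 ± 0.14 (0.00545). LAMB1, another laminin chain, rose by 0.98 ± 0.20, the copper carrier CP by 2.55 ± 0.48 and the peroxidase GPX8 by 0.82 ± 0.16. The fit merged the endothelial labels. In the coronary CD31-positive gate the second coronary label had 49.6% in young and 19.8% in old animals, and the first 41.2% and 66.2%. Single labels were not fitted over both arteries, so a shift between labels cannot be told apart from a change within cells. In fibroblasts 21 genes changed, 4 up and 17 down, of 10423 tested. COL14A1 fell by 1.05 ± 0.17, COL1A1 by 1.99 ± 0.35, COL3A1 by 1.83 ± 0.34, SPARC by 1.14 ± 0.20 and MMP2 by 0.90 ± 0.17, and FOXO3 had -0.77 with limma's adjusted p = 0.0563. In smooth muscle cells 1 gene of 10597 changed, OGN, a small proteoglycan of the matrix, which fell by 0.84 ± 0.15, and FOXO3 had -0.32 with limma's adjusted p = 0.615. These genes were named after their values were seen.

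**Figure D4:**
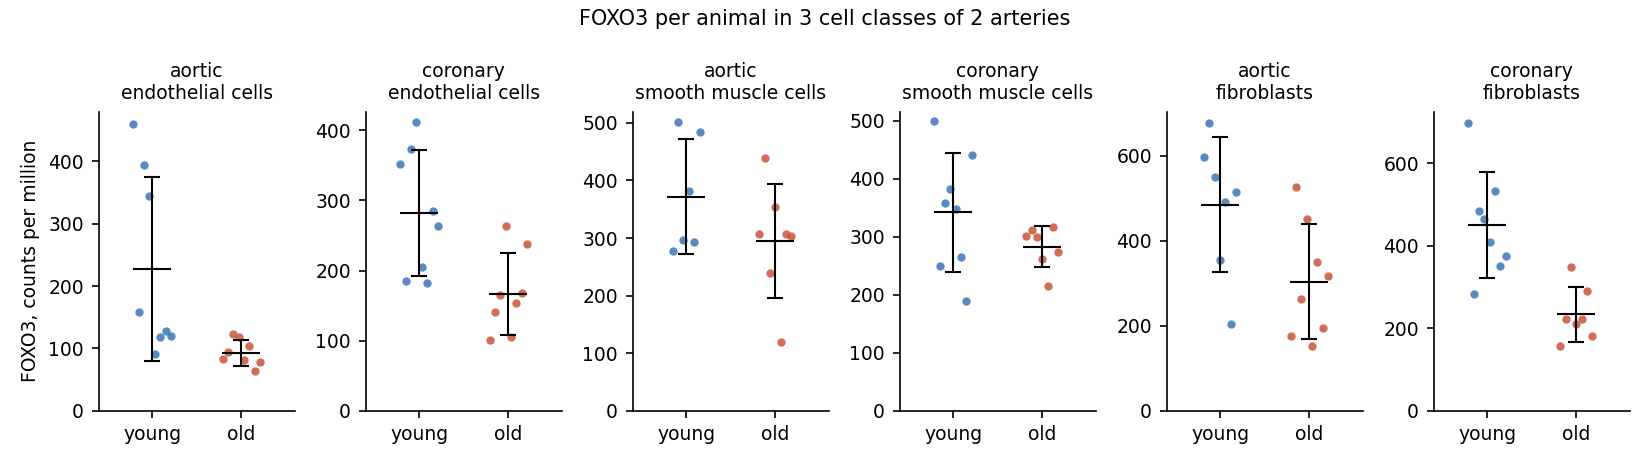
FOXO3 CPM in 3 cell classes of 2 arteries, with 1 point per animal and the mean and SD per age group (6 to 8 animals each). The mean was lower in old animals in all 6 pairs of class and artery, for example 227 against 93.1 CPM in aortic endothelial cells, and no pair passed edgeR's test on its own.

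Endothelial cells of the coronary arteries differed from those of the aorta in 2107 of 11809 genes, 1002 higher and 1105 lower in coronary cells (16 animals each). The matrix protein gene FBLN2 (ENSMFAG00000003835) was higher by 1.88 ± 0.17 on the log2 scale, at 315 ± 129 CPM in the aorta and 1144 ± 345 in the coronary arteries (SD). The lymphangiogenic growth factor VEGFC was higher by 2.69 ± 0.28, at 14.8 ± 9.04 and 97.1 ± 38.4 CPM, and EPAS1, the oxygen-regulated factor HIF-2 alpha, by 0.89 ± 0.11. FTH1, the ferritin heavy chain, had a log2 fold change of -1.18 ± 0.12, at 7435 ± 1941 CPM in the aorta and 3249 ± 712 in the coronary arteries. SOST, a secreted inhibitor of Wnt signals, had -4.97 ± 0.57, at 262 ± 211 and 8.38 ± 9.38 CPM, and FXYD6, a regulator of the sodium pump, -4.40 ± 0.41. The adjusted p of edgeR was 1.76e-09 for FBLN2, 3.12e-08 for VEGFC, 4.49e-07 for EPAS1, 3.93e-09 for FTH1, 7.07e-07 for SOST and 2.78e-08 for FXYD6. Other genes higher in coronary cells were MEF2C (1.99 ± 0.20), PCSK5 (2.07 ± 0.23), FRMD4A (2.03 ± 0.22), UTRN (1.84 ± 0.19), PLCB4 (1.79 ± 0.20), DST (1.44 ± 0.15) and SEPT11 (1.12 ± 0.13). Other genes lower in coronary cells were RAMP1 (-2.68 ± 0.30), SLC36A4 (-2.54 ± 0.29), PRKACB (-1.57 ± 0.19), DOK5 (-1.51 ± 0.19), GPX8 (-1.37 ± 0.17), ARID5B (-1.29 ± 0.15) and LMCD1 (-1.28 ± 0.16). FOXO3 was higher in coronary cells by 0.52 ± 0.17 (adjusted p = 0.0317), while CDKN1A, LMNA, SIRT1 and NOS3 had 0.24 ± 0.27, 0.16 ± 0.12, 0.45 ± 0.24 and -0.33 ± 0.26 and did not pass.

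Genes of VEGF signalling and angiogenesis were higher in coronary endothelial cells in 18 of 26 cases and lower in 1 (20 and 1 adjusted over the list alone), with a median of 0.88 and adjusted p = 0.00099 with an estimated correlation. They included VEGFC, EPAS1, the Notch ligand JAG1 (1.46 ± 0.19) and the VEGF receptor FLT1 (1.76 ± 0.22). Venous and capillary identity genes were higher in 12 of 14 cases (13 adjusted over the list alone), with a median of 1.94 and adjusted p = 0.0202 with an estimated correlation. The venous fate factor NR2F2 had 3.22 ± 0.50, RGCC 3.35 ± 0.56 and the fatty acid binding protein FABP5 1.87 ± 0.32. Arterial identity genes were also higher, in 8 of 14 cases with 1 lower (10 and 2 adjusted over the list alone), with a median of 1.03 and adjusted p = 0.00847 with an estimated correlation. SOX17, JAG2 and HEY1, of the arterial Notch programme, had 1.97 ± 0.25, 2.43 ± 0.32 and 2.91 ± 0.44. Oxidative phosphorylation genes were lower in 27 of 38 cases (31 adjusted over the list alone), with a median of -0.37 and adjusted p = 2.75e-11 with the preset correlation (adjusted p = 0.0548 with an estimated correlation). COX7A1 had -0.74 ± 0.11 and NDUFB10 -0.55 ± 0.10. Of 23 factors of position and developmental origin 3 were higher and 9 lower (5 and 11 adjusted over the list alone), with a median of -0.86 and adjusted p = 0.0712 with an estimated correlation. ISL1, a factor of the second heart field, had 19.5 ± 10.1 CPM in the aorta and 0.102 ± 0.387 in the coronary arteries. Matrix proteases and inhibitors were higher in 11 and lower in 4 of 19 cases, over all genes and adjusted over the list alone, with SERPINE2 (1.28 ± 0.24) and TIMP3 (0.97 ± 0.20) up and the cathepsins CTSB (-0.66 ± 0.13) and CTSK (-0.93 ± 0.21) down (adjusted p = 0.144 with an estimated correlation). The smooth muscle gene TAGLN was higher as well, by 1.59 ± 0.29, with 6 of 13 contractile genes higher and adjusted p = 0.246 with an estimated correlation. A set of 6 smooth muscle marker genes had a median of 64.2 CPM in the second coronary label, 20.9 in the first and 19.3 in the aortic label. Of 33 lists 18 passed with the preset correlation, 3 with an estimated one and 22 by fry. Coronary endothelial cells had fewer UMIs per cell, with medians of 33248 in young and 42147 in old animals against 52507 and 65257 in the aorta, a difference that was not tested.

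Smooth muscle cells of the coronary arteries differed from those of the aorta in 823 of 10597 genes, 400 higher and 423 lower (13 aortic and 15 coronary animals). CAV3 (ENSMFAG00000037376), a muscle caveolin, was higher by 7.09 ± 0.64 on the log2 scale, at 0.635 ± 1.77 CPM in the aorta and 61.8 ± 47.0 in the coronary arteries (SD). MGLL was higher by 3.01 ± 0.28 and the lipocalin APOD by 2.75 ± 0.27, at 518 ± 336 and 3369.5 ± 659.6 CPM. The tropomyosin gene TPM2 was higher by 0.88 ± 0.09, at 8115 ± 1381 and 14772 ± 2149 CPM. LTBP4, which anchors latent TGF-beta and elastic fibres, had -1.23 ± 0.13, at 1332 ± 289 CPM in the aorta and 570.3 ± 129 in the coronary arteries. NPTX2, a neuronal pentraxin, had 60.9 ± 48.5 CPM in the aorta and 0.501 ± 1.02 in the coronary arteries. SOST was lower in this class too (-3.83 ± 0.39). The adjusted p of edgeR was 7.15e-10 for CAV3, MGLL and NPTX2, 9.83e-08 for APOD, 4.75e-09 for TPM2, 4.36e-09 for LTBP4 and 1.87e-07 for SOST. Other genes higher in coronary cells were SRL (5.90 ± 0.67), CRIP2 (2.37 ± 0.26), MAPRE2 (1.77 ± 0.20), C1QTNF1 (1.69 ± 0.18) and SPARCL1 (1.04 ± 0.12). Other genes lower in coronary cells were CDON (-2.42 ± 0.29), AQP1 (-1.99 ± 0.20), CD34 (-1.87 ± 0.22), ITM2C (-1.87 ± 0.23), RGCC (-1.76 ± 0.21), CPE (-1.35 ± 0.14) and MAP1B (-1.12 ± 0.10). The cell cycle inhibitor CDKN1A was higher in coronary cells by 1.18 ± 0.25 (adjusted p = 0.00202), at 208 ± 144 and 449.7 ± 138 CPM, while FOXO3, LMNA, SIRT1 and NOS3 had 0.02 ± 0.15, 0.17 ± 0.14, 0.45 ± 0.33 and 1.15 ± 0.91 and did not pass.

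Contractile genes were higher in coronary smooth muscle cells in 10 of 14 cases (11 adjusted over the list alone), with a median of 0.67 and adjusted p = 0.00233 with an estimated correlation. MYH11, the smooth muscle myosin heavy chain, had 0.81 ± 0.10, the intermediate filament desmin (DES) 3.93 ± 0.45 and MYL9 0.75 ± 0.12. Elastic fibre genes were lower in 7 of 14 cases (9 adjusted over the list alone), with a median of -1.13 and adjusted p = 0.00425 with an estimated correlation. FBLN5, which assembles elastic fibres, had -3.32 ± 0.37, at 726 ± 242 CPM in the aorta and 76.1 ± 51.6 in the coronary arteries, and EFEMP1 had -2.94 ± 0.39. Oxidative phosphorylation genes were higher in 16 of 38 cases (25 adjusted over the list alone), with a median of 0.43 and adjusted p = 0.00431 with an estimated correlation, such as NDUFA1 (0.75 ± 0.13) and COX7C (0.67 ± 0.13). Of 5 cardiomyocyte genes 4 were higher and 1 lower (also adjusted over the list alone), with a median of 4.01 and adjusted p = 0.00839 with an estimated correlation. ACTC1, the cardiac actin, had 5.37 ± 0.52, at 20.2 ± 18.6 and 736 ± 597 CPM, and the cardiac troponin TNNT2 had 7.24 ± 0.81. A set of 3 cardiomyocyte marker genes had a median of 374.7 CPM in the coronary smooth muscle label. It had 19.2 CPM in the aortic smooth muscle label and 6.26 in the fibroblast label. Cardiomyocyte RNA among the coronary cells was not tested as a source, neither for these genes nor for others higher in this class. Of 18 factors of position and origin 3 were higher and 6 lower (4 and 7 adjusted over the list alone), though the list as a whole did not pass (adjusted p = 0.374 with the preset correlation). TCF21 had 2.91 ± 0.54, TBX2 2.37 ± 0.44 and HOXB4 -4.43 ± 0.86, and HOXA2 had 12.7 ± 9.33 CPM in the aorta and 0.202 ± 0.596 in the coronary arteries. Fibroblast identity genes had a median of -1.02, with 5 of 15 lower, and adjusted p = 0.159 with an estimated correlation. Of 34 lists 14 passed with the preset correlation, 4 with an estimated one and 15 by fry.

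Fibroblasts differed between the arteries in 265 of 10423 genes, 131 higher and 134 lower in coronary cells (15 animals each). CTSD (ENSMFAG00000002481), a lysosomal protease, was higher by 1.76 ± 0.17 on the log2 scale, at 522 ± 158 CPM in the aorta and 1748 ± 736 in the coronary arteries (SD). The proteoglycan genes LUM, BGN and VCAN were higher by 1.68 ± 0.19, 1.44 ± 0.18 and 1.38 ± 0.18, with LUM at 1235 ± 569 and 3754 ± 990.4 CPM. The protease inhibitors TIMP1, TFPI and SERPINE2 were higher by 1.11 ± 0.14, 1.5 ± 0.19 and 2.56 ± 0.32. MGP, an inhibitor of calcification, was higher by 0.89 ± 0.13, and SORBS2, an adaptor of the cytoskeleton, by 4.60 ± 0.67. PEBP4 had -2.10 ± 0.25, at 1513 ± 367 CPM in the aorta and 353 ± 190.4 in the coronary arteries, and the guidance cue SEMA3C had -1.43 ± 0.20. The adjusted p of edgeR was 1.15e-09 for CTSD, 5.83e-07 for LUM, 1.81e-06 for PEBP4 and 8.78e-06 for SERPINE2, MGP and SEMA3C. Other genes lower in coronary cells were BCHE (-4.05 ± 0.68), LMO3 (-3.91 ± 0.62), SLC29A1 (-1.27 ± 0.19), PDGFRL (-1.22 ± 0.19), CHRDL1 (-1.19 ± 0.19), SCARA5 (-1.05 ± 0.17) and IGFBP6 (-0.90 ± 0.14). FOXO3, CDKN1A, LMNA and SIRT1 had -0.22 ± 0.17, 0.11 ± 0.32, 0.55 ± 0.18 and -0.34 ± 0.39 and did not pass.

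Collagen genes were higher in coronary fibroblasts in 6 of 23 cases (12 adjusted over the list alone), with all 23 positive, a median of 0.71 and adjusted p = 0.00353 with an estimated correlation. The basement membrane chain COL4A2 had 1.33 ± 0.22, COL14A1 0.77 ± 0.18 and COL15A1 2.11 ± 0.51. Genes of TGF-beta signalling and endothelial-to-mesenchymal transition were higher in 5 of 31 cases and lower in 0 (9 and 1 adjusted over the list alone), with a median of 0.41 and adjusted p = 0.00423 with an estimated correlation. The growth factor CTGF had 1.41 ± 0.19, fibronectin (FN1) 0.80 ± 0.15 and TGFB2 0.94 ± 0.23. Of 18 factors of position and origin 4 were higher and 5 lower (6 and 6 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.688 with the preset correlation). TCF21, a factor of epicardial and fibroblast fate, had 3.40 ± 0.48, MEOX1 3.74 ± 0.68 and PRRX1 -0.97 ± 0.15, and HOXA5 had 10.5 ± 11.8 CPM in the aorta and 0.0516 ± 0.136 in the coronary arteries. Of 20 matrix proteases and inhibitors 4 were higher and 3 lower (4 and 5 adjusted over the list alone), with CTSK at -0.68 ± 0.13. Camera placed that list higher (adjusted p = 0.0275, and adjusted p = 0.0854 with an estimated correlation) while its median was -0.09. Of 34 lists 10 passed with the preset correlation, 2 with an estimated one and 5 by fry. The count of genes was 441 with DESeq2 (261 higher, 180 lower), 445 with no filter and 144 with at least 20 cells per animal. With the animal as a block 342 genes passed, 123 higher and 219 lower, and the block shifted the median fold change of all genes by -0.16.

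**Figure D5:**
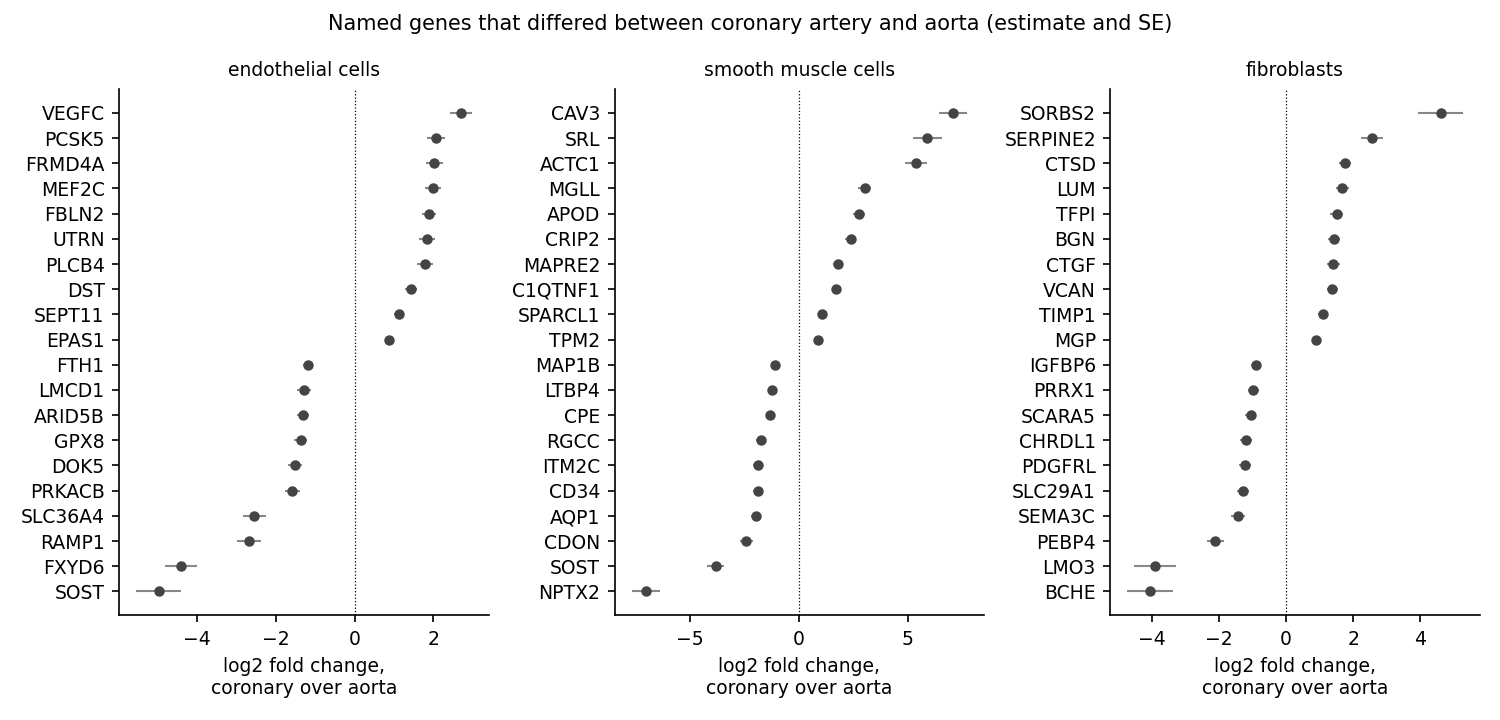
Log2 fold change, coronary over aorta, of the named genes in endothelial cells (16 animals), smooth muscle cells (13 aortic and 15 coronary animals) and fibroblasts (15 animals), with bars for the SE. All genes drawn passed edgeR's test, with SOST lower in coronary cells in both endothelial cells (-4.97) and smooth muscle cells (-3.83).

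No gene showed a change with age that differed between the arteries by edgeR's interaction term. The term was fitted without the animal as a block, although both arteries came from the same animals. In simulation the arteries of an animal were drawn independently of each other. There the same fit recovered 10%, 3% and 0% of 2-fold interactions in endothelial cells, smooth muscle cells and fibroblasts. The lack of calls therefore says little about differences of that size. Of 12023 genes in endothelial cells, 11207 in smooth muscle cells and 10704 in fibroblasts, 509, 511 and 423 had an unadjusted p under 0.05 where chance gives 601, 560 and 535, and DESeq2 called 2, 10 and 4. The smallest p in endothelial cells belonged to TSHZ2 (-5.86 ± 1.31, adjusted p = 0.523) and E2F4 (1.24 ± 0.28), followed by MFSD11 (1.78 ± 0.43), LAMB2 (0.85 ± 0.22) and PDE7B (-1.74 ± 0.46). In smooth muscle cells they belonged to MGLL (-1.94 ± 0.41, adjusted p = 0.319), CAVIN1 (-0.80 ± 0.20), LGR6, AREG and S100A9. In fibroblasts they belonged to THBS4, RAB21, SLC26A7, CPAMD8 and COL10A1, with a smallest adjusted p of 0.69. With at least 20 cells per animal 1 gene passed in fibroblasts.

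No gene showed a change with age that differed between the sexes by edgeR's interaction term in any of the 6 pairs of class and artery. The genes with an unadjusted p under 0.05 numbered 904 in aortic and 438 in coronary endothelial cells, 420 and 487 in smooth muscle cells and 528 and 522 in fibroblasts, where chance gives 615 and 586, 528 and 560, and 562 and 478, and no other tool was run. The other classes were too small per animal for tests. Immune cells reached 10 cells in 3 young and 3 old animals in the aorta, and in 1 young and 4 old animals in the coronary arteries. Lymphatic endothelial-like cells did so in 3 young and 4 old animals in the coronary arteries, and epicardial cells in 1 old animal in the aorta.

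No difference in UMIs or genes per cell between the age groups passed the exact permutation tests in any class. In aortic endothelial cells the median was 52507 ± 18091 UMIs in young and 65257 ± 22174 in old animals (SD, n = 8 each; exact permutation p = 0.228, adjusted 0.583), with 3122 ± 326 and 3347 ± 366 genes (adjusted 0.42). No difference in cell-to-cell variability passed either. It was 0.496 ± 0.038 in young and 0.464 ± 0.021 in old aortic endothelial cells (SD, n = 8 each; exact permutation p = 0.0567, adjusted over 6 tests 0.34).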

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

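Chosen only after the result was seen were the tests of the other fibroblast identity genes, of COL1A1 with 10 cells drawn, of FOXO3 and the collagens per animal and of depth outside aortic endothelial cells for FOXO3 and ribosomal protein genes, as well as the fit of both arteries. The exact permutation tests of values per animal, including those of glucocorticoid-induced genes, form 1 family of 10. Values per animal use the class and artery pairs with at least 10 cells, so fibroblasts of CE07 rest on the coronary arteries alone (8 aortic cells) and those of CE10, the lowest old collagen value, on the aorta alone (0 coronary cells).

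The lower collagen RNA of old animals was weighed as 1 pattern. In fibroblasts of both arteries together the collagens' percent of counts had a mean log2 difference of -1.08, with 8 of 8 old animals below the young median (exact permutation p = 0.00202, adjusted 0.0101). The list was picked for this test from the same animals, so the p is no independent support. Abundant chains weigh most in such a percent, with COL1A1, COL1A2 and COL3A1 at means of 2197, 1689 and 1195 CPM. The difference therefore does not describe collagen genes in general. In coronary fibroblasts a loss of fibroblasts among the cells called so would lower their other identity genes too, but these had a median of 0.23 over 13 genes, 5 of them negative. COL1A1 there had -1.86 ± 0.26 with 10 cells drawn per animal and -1.52 ± 0.26 with the median UMIs per cell as a covariate. Young and old animals were already close on average, with 27.5 and 25.6 coronary fibroblasts per animal and 53282 and 48792 median UMIs. Both fits therefore had little to remove and say little about unequal cell numbers or depth. In coronary smooth muscle cells the other fibroblast identity genes lay the same way as the collagens, with a median of -1.09 over 13 genes and 12 negative, which is consistent with fibroblast RNA among young cells as the source there. A biological difference with age stays open, as does any difference in how young and old tissue digested, which was not tested.

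FOXO3 was lower in old animals in all 6 pairs of class and artery, and the mean of its log2 value per animal differed by -0.70 (exact permutation p = 0.00186, adjusted over the family 0.0101, over the 5 fixed genes 0.00932), with 8 of 8 old animals below the young median. That p argues against chance among the 16 animals, while the same test gave 0.195 for CDKN1A, 0.174 for LMNA, 0.295 for SIRT1 and 0.914 for NOS3. These means took in all 6 pairs without the filter on low counts. In coronary smooth muscle cells of young animals other than CE14, NOS3 lay at 0 to 6.93 CPM, so its p is a weak contrast to FOXO3. A fault shared by genes whose annotation the authors added would move the 10 others tested, and their mean log2 fold changes had a median of -0.025 with 5 negative. Depth as the whole cause is argued against in endothelial cells. With the median UMIs per cell as a covariate FOXO3 had -1.04 ± 0.23 in aortic and -0.70 ± 0.23 in coronary endothelial cells. In aortic and coronary fibroblasts it had -0.67 ± 0.25 and -0.92 ± 0.25. Median UMIs of young and old fibroblasts were close, at 64188 and 66282 in the aorta and 53282 and 48792 in the coronary arteries. The covariate therefore had little to remove in that class. In smooth muscle cells FOXO3 lay within 2 standard errors of 0 with the covariate (-0.10 ± 0.25 in the aorta, -0.34 ± 0.19 in the coronary arteries). It did so without the covariate as well (-0.36 ± 0.25 and -0.28 ± 0.19), so depth cannot be told apart in smooth muscle cells. Lower FOXO3 with age in endothelial cells and fibroblasts may be a biological difference, as a hypothesis found and tested on the same animals. Any difference in how young and old tissue digested was not tested. Fits of single endothelial labels also gave FOXO3 a negative log2 fold change, but a shift between labels was not tested as a cause.

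Ribosomal protein genes passed camera with the preset correlation in 5 of the 6 age comparisons, with medians from 0.03 to 0.35, and in 0 with an estimated correlation, where the lowest adjusted p was 0.339. The mean log2 percent of counts on them per animal differed by 0.20, with 7 of 8 old animals above the young median (exact permutation p = 0.043, adjusted 0.0919). The criterion written beforehand was a p under 0.05 without adjustment, which would have excluded chance. It was set aside because the test is 1 of 10 in its family, so chance movement of genes that vary together cannot be told apart from a change with age. Depth alone is argued against where the median UMIs per cell as a covariate left most of the median, from 0.26 to 0.25 in aortic and 0.25 to 0.22 in coronary endothelial cells, 0.26 to 0.29 in coronary smooth muscle cells and 0.35 to 0.33 in coronary fibroblasts, but it took it from 0.15 to 0.096 in aortic smooth muscle cells and from 0.030 to 0.020 in aortic fibroblasts, where depth cannot be told apart from a change with age.

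The counts of changed genes and of lists were set against other splits of the same animals, 40 splits in each case with the real one included and 20 for interactions. A share of 1 of 40 is the lowest that 40 splits can give, and the shares were not adjusted over the comparisons. Chance is argued against, but not excluded, for the genes changed by age in aortic endothelial cells (1 of 40 splits gave as many, real 6, highest other 1). In coronary fibroblasts the share was as low (1 of 40, real 1, highest other 0), but a single gene against 0 is little evidence against chance. It cannot be excluded in coronary endothelial cells (3 of 40, real 1, highest other 2). For the real counts of 0 in aortic smooth muscle cells, coronary smooth muscle cells and aortic fibroblasts (highest other 33, 2 and 1) the outcome of 40 of 40 was certain and says nothing about chance. The 33 genes came from 1 split of aortic smooth muscle cells, which may point to a structure of those samples other than age or to an unstable fit, and neither was tested. For lists past the threshold by age, chance cannot be excluded in any comparison. In aortic and coronary endothelial cells 37 and 5 of 40 splits gave as many (real 2 and 9, highest other 8 and 12). In aortic and coronary smooth muscle cells it was 17 and 21 (real 7 and 6, highest other 16 and 20), and in aortic and coronary fibroblasts 15 and 16 (real 6 and 5, highest other 9 and 7). Chance is argued against for the genes that differed between arteries, with 1 of 40 splits in each class. The real counts were 2107, 823 and 265 and the highest others 0, 103 and 1. For lists chance is argued against in endothelial cells (1 of 40, real 18, highest other 13). It cannot be excluded in smooth muscle cells (2 of 40, real 14, highest other 14) or fibroblasts (2 of 40, real 10, highest other 10). For the age by artery interaction (real 0, highest other 1, 0 and 1) the 20 splits are too few for a share under 0.05, and 20 of 20 was certain with a real count of 0. The same holds for sex by age (real 0, highest other 1 and 13 in endothelial cells, 0 and 2 in smooth muscle cells, 1 and 4 in fibroblasts). With both arteries in 1 fit, chance is argued against in endothelial cells (1 of 40, real 125, highest other 4). It cannot be excluded in smooth muscle cells (6 of 40, real 1, highest other 3). In fibroblasts the share was low (1 of 40, real 21, highest other 20), but another split came within 1 gene of the real one, so chance stays open there.

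Of 149 groups of animals 20 held a value far from the others of its group, where chance gives about 1 in 20 groups if values are normally distributed. The values were percents with many zeros, UMIs, genes and CPM, none of them transformed, and the same animals recur. The 20 groups therefore cannot be read as an excess over chance. Young animal CE04 had 3656.5 median genes per coronary endothelial cell (others 2137 to 2820.0). Young CE08 had 149480.0 median UMIs per aortic smooth muscle cell (others 46621 to 71824). Old CE10 had 102670.0 UMIs (others 37319 to 55563) and 3994 genes (others 2445 to 3021.5) per coronary smooth muscle cell. Old CE17 had 4830.0 genes per aortic fibroblast (others 2702 to 3652). In the aortic CD31-positive gate the first coronary label had 17.3% in old CE03 (others 0.552% to 3.95%), and the second had 36.2% in old CE17 (others 1.66% to 15.1%). In the aortic CD31-negative gate epicardial cells had 27.3% in old CE09 (others 0% to 3.53%). In the coronary CD31-positive gate the aortic label had 2.35% in young CE05 (others 0% to 0.629%), and lymphatic endothelial-like cells had 26.9% in old CE03 (others 0.671% to 9.09%). In the coronary CD31-negative gate fibroblasts had 90.6% in old CE03 (others 0% to 28.6%). CDKN1A had 194 CPM in aortic endothelial cells of young CE04 (others 37.0 to 93.4) and 386 CPM in its aortic fibroblasts (others 38.95 to 164). SIRT1 had 92.6 CPM in coronary endothelial cells of young CE14 (others 16.9 to 49.9), 102 CPM in aortic smooth muscle cells of old CE09 (others 7.60 to 42.1), 88.9 CPM in aortic fibroblasts of young CE04 (others 10.0 to 38.8) and 92.8 CPM in coronary fibroblasts of young CE14 (others 4.40 to 42.8). MT1X had 3668 CPM in coronary endothelial cells of young CE08 (others 679 to 1397), and without that animal its adjusted p was 7.86e-05. NOS3 had 24.7 CPM in coronary smooth muscle cells of young CE14 (others 0 to 6.93), and COL1A2 had 438 CPM in coronary smooth muscle cells of old CE09 (others 107 to 199.7).

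Some lists had an age change that differed between the arteries by camera with the preset correlation, and 0 of them did with an estimated correlation. In endothelial cells the coronary change was the higher one for osteochondrogenic genes (adjusted p = 0.0426, and adjusted p = 0.287 with an estimated correlation) and arterial identity genes (0.0193, and 0.287), and the lower one for venous and capillary genes (0.0193, and 0.803). In smooth muscle cells it was higher for immediate early (0.00631, and 0.519), inflammatory (0.0041, and 0.519), interferon (0.04995, and 0.587) and antigen presentation genes (0.00768, and 0.519), and lower for elastic fibre genes (0.04995, and 0.519). In fibroblasts it was higher for ribosomal (2.51e-12, and 0.83), inflammatory (0.0027, and 0.578), oxidative phosphorylation (0.00274, and 0.514) and osteochondrogenic genes (0.0103, and 0.474), and lower for contractile (0.00274, and 0.83) and mitochondrial transcripts (0.0469, and 0.83). With the animal as a replicate block the 3 lists of endothelial cells still passed, but the interferon genes of smooth muscle cells did not (adjusted p = 0.0927), nor did any of the 6 lists of fibroblasts except the ribosomal genes (adjusted p = 5.06e-14).

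Among cells outside all comparisons, 354 of the 413 that reached the minima of annotated cells without having a label showed the marker level of exactly 1 class. The median of all 413 was 7563 UMIs, against 45728.5 for annotated endothelial cells. Cells without a label were 8.76% of young and 7.22% of old aortic cells and 15.2% and 17.2% of coronary cells.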

How the results depend on the processing

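Tests chosen only after the data were seen are the fits of single labels and those with lymphatic endothelial-like cells. Over all alternatives 163 values of comparisons kept their direction and side of the threshold or lay within 1.5 times of a count, 85 moved further, 2 came to pass the threshold and 4 turned their direction. Of the values of single genes and lists 3152 kept both, 111 came to pass, 51 no longer passed and 56 turned. The cause was not tested except where the setting itself lowers the number of cells or genes. A fit of the second deposited table was not run, because its counts were equal wherever compared. In the order aortic and coronary endothelial cells, aortic and coronary smooth muscle cells, aortic and coronary fibroblasts, DESeq2 called 76, 80, 34, 15, 10 and 14 genes for age where edgeR called 6, 1, 0, 0, 0 and 1. It called 2, 10 and 4 for the age by artery interaction in endothelial cells, smooth muscle cells and fibroblasts, where edgeR called 0, and 441 for arteries in fibroblasts, where edgeR called 265. Without a filter on low counts the age counts were 13 and 5 in endothelial cells, 19 and 1 in smooth muscle cells and 13 in coronary fibroblasts, the artery count in fibroblasts was 445, and SIRT1 in aortic smooth muscle cells had -0.012 where it had 0.03. With at least 20 cells per animal, which leaves fewer animals, the counts were 4 in coronary endothelial cells and 0 in coronary fibroblasts (4 young and 3 old animals). They were 1 for the interaction in fibroblasts and 144 for arteries in fibroblasts. SIRT1 in aortic smooth muscle cells then had -0.24, and FOXO3 between arteries in smooth muscle cells -0.047. With limma-trend on means over cells the counts were 11 in aortic endothelial cells, 7 and 2 in smooth muscle cells, and 2 and 11 in fibroblasts. That setting moved the median fold change of all genes by 0.12 in aortic endothelial cells, -0.22 and -0.16 in aortic and coronary smooth muscle cells and -0.16 in coronary fibroblasts. Under it CDKN1A turned to -0.15 in aortic fibroblasts, -0.19 in coronary endothelial cells and -0.44 in coronary fibroblasts, LMNA to 0.078 in coronary fibroblasts and -0.31 in coronary smooth muscle cells, NOS3 to 0.056 in coronary smooth muscle cells, and SIRT1 to -0.032 in aortic fibroblasts and -0.62 in aortic smooth muscle cells. With 10 cells drawn per animal 2 genes passed in aortic endothelial cells, and LAMB2, MERTK and LIFR were no longer among those called. CDKN1A then turned to -0.49 in aortic fibroblasts and -0.73 in coronary endothelial cells, LMNA to -0.081 in aortic endothelial cells and SIRT1 to -0.71 in aortic fibroblasts. With age in years 11 genes passed in aortic endothelial cells and SIRT1 in aortic smooth muscle cells had -0.039. With 1 gate only SIRT1 in aortic smooth muscle cells had -0.44. In coronary endothelial cells 3 genes passed with RLE size factors, 2 without the sex covariate and 2 with lymphatic endothelial-like cells, and without the sex covariate CDKN1A in aortic fibroblasts had -0.027. In cells of the first coronary label alone 2 genes passed, FBLN5 had -0.048 and NOS3 -0.11. In those of the second 0 passed and NR2F2 had 0.069. With the aortic endothelial label alone LMNA had -0.024, and with the aortic smooth muscle label alone SIRT1 had -0.45. With both gates together the difference of shares turned to -2.02 percentage points for aortic fibroblasts (1.83 in 1 gate), 2.24 for the aortic label in the aorta (-4.74) and -14.0 for the second coronary label in the coronary arteries (0.0922 in the CD31-negative gate, but -29.8 in the CD31-positive gate, the same way). That of the aortic label in the coronary arteries was 1.94 and that of the first coronary label 21.1, both then past the threshold. Pooled shares also depend on how many cells of each gate an animal gave. The mean of UMIs over aortic fibroblasts differed by -3105 between old and young animals where the median differed by 2094.

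With an estimated correlation camera passed 0 lists in each of the 6 age comparisons, where the preset correlation passed 2, 9, 7, 6, 6 and 5. It passed 0 in the 3 interactions (preset 3, 5 and 6) and 3, 4 and 2 between arteries (preset 18, 14 and 10). Fry passed 0 lists in the age comparisons and the interactions and 5 between arteries in fibroblasts, where it gave the positional factors the other direction (adjusted p = 0.918). With the animal as a replicate block the age by artery lists numbered 5, 8 and 1, and FOXO3 between arteries in smooth muscle cells had -0.10 where it had 0.02. With that pairing 2399, 779 and 342 genes differed between arteries in endothelial cells, smooth muscle cells and fibroblasts, of which only 1947, 649 and 226 were among the 2107, 823 and 265 called without it. With each animal left out in turn the age counts ranged from 4 to 16 in aortic and 1 to 8 in coronary endothelial cells, 0 to 8 and 0 to 1 in smooth muscle cells, and 0 to 4 and 0 to 2 in fibroblasts. SIRT1 ranged from -0.49 (without CE09) to 0.27 (without CE03) in aortic smooth muscle cells, from -0.17 to 0.044 in aortic endothelial cells and from -0.12 to 0.56 in aortic fibroblasts. CDKN1A ranged from -0.36 to 0.40 in aortic fibroblasts and from -0.12 to 0.35 in coronary endothelial cells. LMNA ranged from -0.052 to 0.14 in aortic endothelial cells and from -0.14 to 0.13 in coronary fibroblasts. NOS3 ranged from -0.20 to 0.11 in aortic endothelial cells and from -0.82 to 1.03 in coronary smooth muscle cells. The depth, the spread and the number of animals together limit what was detectable, with 35% to 67% of simulated 4-fold age changes and 3% to 33% of 2-fold ones recovered.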

Other observations

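Chosen only after the result was seen were the fit of both arteries, the spike-in ratio and the test of the glucocorticoid list in fibroblasts and smooth muscle cells.

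Coronary endothelial cells were also higher in 5 of 6 lymphatic genes (5 adjusted over the list alone), with a median of 2.98 (camera adjusted p = 1.49e-05, and adjusted p = 0.0548 with an estimated correlation). They included the VEGFC receptor FLT4 (3.34 ± 0.50), MMRN1 (2.74 ± 0.62) and the chemokine CCL21 (1.71 ± 0.52), although cells labelled lymphatic endothelial-like were left out. The level differed between the 2 coronary labels. A set of 4 lymphatic marker genes had a median of 26.7 CPM in the second coronary label, 4.15 in the first and 6.31 in the aortic label. Ribosomal protein genes were lower in 33 of 54 cases (45 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 7.97e-14, and adjusted p = 0.19 with an estimated correlation). Of 7 pericyte genes in smooth muscle cells 1 was higher in coronary cells, the receptor NOTCH3 (2.05 ± 0.45), and 1 lower (the same adjusted over the list alone), and the list did not pass (adjusted p = 0.769 with the preset correlation). The lower gene was RGS5, a regulator of G protein signals that marks pericytes, with a log2 fold change of -3.77 ± 0.40, at 2499.9 ± 509.8 CPM in the aorta and 211 ± 189 in the coronary arteries (SD; adjusted p = 6.19e-07 by edgeR, 13 and 15 animals).

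MT1X, ZBTB16 and TSC22D3, which fell in old endothelial cells with both arteries in 1 fit, are genes that glucocorticoids are known to induce. A candidate explanation is a lower glucocorticoid response in old animals. A list of other such genes was written down before their values were looked at, and its mean log2 value per animal differed by -0.27 in endothelial cells, with 7 of 8 old animals below the young median (exact permutation p = 0.0552, adjusted 0.0919). By the criterion written beforehand, a p of 0.05 or more, the prediction was not met. It was called undecided because a p that misses the threshold excludes nothing, and the hypothesis cannot be told apart from chance here. Of its members FKBP5, a chaperone of the receptor, had -1.40 ± 0.32 in aortic endothelial cells (adjusted p = 0.127) and -0.80 in coronary endothelial cells. In the same order GLUL had -0.60 and -0.85, PER1 -0.37 and -0.40 and SGK1 -0.44 and -0.49. DUSP1 went the other way with 0.26 and 0.71. In aortic endothelial cells CEBPD (0.54) and ERRFI1 (0.22) were positive too. KLF9 (-0.62), NFKBIA (-0.38), KLF15 (-1.07), METTL7A (-0.44) and ANGPTL4 (-0.05) were negative there. The same list differed by -0.48 in fibroblasts (exact permutation p = 0.0135, adjusted 0.0451) and by -0.39 in smooth muscle cells (exact permutation p = 0.0493, adjusted 0.0919, so not past the threshold), which the prediction did not cover.

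The ratio of gene UMIs to spike-in UMIs in aortic endothelial cells was 9.57 ± 1.99 in young and 12.8 ± 1.70 in old animals (SD, n = 8 each; exact permutation p = 0.00218, adjusted over 6 tests 0.0131). It was 7.37 ± 1.44 and 9.003 ± 2.21 in coronary endothelial cells (exact permutation p = 0.102, adjusted 0.293). Spike-in sequences took 9.11% of all UMIs of annotated cells. The fold changes in this report, including those of LAMB2, MERTK, LIFR, FOXO3 and the ribosomal protein genes in these cells, are of shares of counts and were not rescaled by this ratio.

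The genes whose p was smallest for age in endothelial cells with both arteries in 1 fit also held CAVIN2, a coat protein of caveolae, which fell by 0.80, and LIFR, which fell by 1.04 ± 0.16. HAPLN3, a link protein of hyaluronan, rose by 1.19 and the retinal dehydrogenase ALDH1A1 by 1.15. In fibroblasts COL15A1 fell by 1.77, COL1A2 by 1.35 ± 0.26 and the secreted protein CRISPLD2 by 1.09. These genes were named after their values were seen.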
